A study of Mus musculus with 12 samples.

How the data were processed

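SMART-seq, a full-length RNA sequencing protocol, was run on mouse aortic endothelial cells, per the series text. The 12 libraries fell into 4 groups of 3, and each title joins the names of 2 diets. The first diet of a title was read as the mother's and the second as the offspring's, after the order in which the series text writes the same groups; the titles themselves do not say so. CD and WD are kept as the labels give them. The series title speaks of a maternal high-fat diet and of atherosclerosis in the offspring, and per the series text the offspring on WD had been given WD again for 4 weeks. The labels give no genotype, sex, age, sorting step or batch. They also do not say whether the replicates came from separate animals, so the p-values of single genes measure only the spread between these samples, which may be technical.

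Per the submitters' processing notes, the reads were handled with FastQC 0.12.1, Trim Galore 0.6.10, HISAT2 2.2.1, SAMtools 1.13, featureCounts 2.0.1 and DESeq2, on the GRCm38 (mm10) genome. The order of these steps, their settings, the handling of strand and of reads that match several genes, and the rule by which genes were kept are not given in the sources used here. The authors deposited 1 table of 10655 genes, with a normalised signal per gene and library. The values were counts divided by a size factor per library: 100% of the 127860 values came out as whole multiples of the value of 1 read, within a tolerance of 0.01. In CD_CD replicate 3 the lowest value was taken as 3 reads, since the spacing of the values required it. The size factors equalled those of the median of ratios over 9491 genes with reads in every library, up to 1 constant. The authors' deposited table also holds a log2 fold change, a p-value and an adjusted p-value per gene for both comparisons of the mothers' diets. Of the gene symbols, 18 had been turned into dates and 1 occurred more than once; these were left as they stood. Every gene had reads in at least 9 of the 12 libraries, and the lowest mean was 15.8. Other assays that the series text mentions were not analysed here.

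All tests started from the deposited normalised values. They were put on a log2 scale after a pseudocount of 1 was added, so that fold changes understate the change of low genes. The test planned for counts was edgeR's quasi-likelihood test, with limma on log2 values as the stated fallback for any other unit; since the deposited values were not counts, limma 3.58.1 with a mean-variance trend was the test (R 4.3.3). The planned filter, a mean value of at least 1, removed 0 genes. All 12 libraries entered 1 model with a mean per group, which leaves 8 residual degrees of freedom. Benjamini-Hochberg adjusted p-values under 0.05 were called, and a gene is said to have risen or fallen only where it passed. The 5 contrasts were the mother's diet in CD offspring, the mother's diet in WD offspring, the offspring's diet with CD mothers, the offspring's diet with WD mothers, and the difference between both effects of the mother's diet (the interaction). The agreement of both effects of the mother's diet was measured as Pearson's r and Spearman's rho across genes, with a two-sided exact permutation p from all 400 arrangements of the libraries within each offspring diet. Genes are not independent replicates in such an r.

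Fixed in advance were 41 gene lists, for pathways of endothelial cells and for cell types that an aortic preparation can hold. Of these, 39 were tested. The list of mitochondrially encoded genes had 0 members in the table, and the sex-linked list had 1, Xist, whose levels are given per group of libraries. Lists were tested with limma's camera at a preset correlation between genes of 0.01, and again with a correlation estimated from the data and with fry, which asks whether the genes of a list move one way and compares them with no other genes. At the preset value the members of a list count as nearly independent, so that p reflects spread across genes as well as samples. Estimated correlations were far higher for many lists, such as 0.936 for ribosomal protein, 0.643 for pan-endothelial and 0.555 for smooth muscle genes. Per list, the members past the threshold are counted over all genes tested and, as members adjusted over the list alone, within the list. Whether a list is higher or lower depends on the scaling: the deposited size factors centre each library on its typical gene.

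The genes named were set by a rule. For the mother's diet these were the 10 largest rises and 10 largest falls among genes past the threshold with a mean of at least 5, no overlap between the libraries of both groups and a gene symbol that is not a clone or model name. For the offspring's diet it was 6 in each direction, and for the interaction 3. Where fewer than 5 passed in a direction, the 5 with the smallest p are named as not having passed. Up to 4 members with the smallest p are added for each list that passes or has a member that does, and 17 of 18 panel genes of adhesion, flow response, AP-1 and lipid handling are described for the mother's diet whatever their p. The samples, contrasts, tests, gene lists, naming rule and most alternatives were set before the data were examined.

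Alternatives set then were quantile normalisation, no filter, a pseudocount of 0.1, DESeq2 1.42.0 on the recovered reads, the replicate number as a block, a fit to only the 6 libraries compared, and each library left out in turn. Others were chosen after seeing the data: edgeR 4.0.16 on the recovered reads, scaling by library totals, removal of the trend with gene length (lowess, span 0.3), and leaving out CD_WD replicate 1 and WD_CD replicate 3, which stood apart from their groups. Gene positions, lengths and GC content came from the GENCODE mouse release M21 annotation of GRCm38 (rtracklayer 1.62.0, Biostrings 2.70.1); lengths are of the union of exons, for 10292 genes (96.6%). Positions are 1-based.

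The procedures were tested on simulated counts with 200 of 10655 genes changed. At a 16-fold change, the test recovered 73% of them for the mother's diet in CD offspring, 72% in WD offspring, 74.5% for the offspring's diet with CD mothers and 70% with WD mothers. At a 4-fold change the shares were 10%, 1%, 0.5% and 6.5%. A level of 0 reads was bounded by 3 reads per library, which is 1.04 to 11.9 normalised counts, and ratios to a group with 1 to 3 reads carry a 95% counting interval. Both cover counting error only, since the reads carry no molecular identifiers. Ribosomal protein, histone and H2 genes have near-identical copies, so their values are uncertain.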

Results

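RNA from aortic endothelial cells was sequenced in 12 libraries: 3 each from CD offspring of CD mothers (CD_CD), CD offspring of WD mothers (WD_CD), WD offspring of CD mothers (CD_WD) and WD offspring of WD mothers (WD_WD). Normalised read counts were available for 10655 genes. The reads in these genes numbered 19670570, 17188843 and 16966696 in CD_CD, 16888763, 17222566 and 10667657 in WD_CD, 11264156, 7184178 and 18013966 in CD_WD, and 7967665, 12487609 and 4074413 in WD_WD. The 20 genes with most reads took 12.9% to 14.4% of the reads in CD offspring and 35.4% to 46.2% in WD offspring. Rn45s, the ribosomal RNA precursor, had most reads in each library of CD offspring. In WD offspring Ftl1, the ferritin light chain, led in CD_WD replicate 3 and WD_WD replicates 1 and 2, Cd74, the invariant chain of MHC class II, in CD_WD replicate 1, and Rn45s in CD_WD replicate 2 and WD_WD replicate 3. Rn45s took 2.2% to 3.58% of the reads in CD offspring and 0.543% to 7.71% in WD offspring. Xist, the RNA of the inactive X chromosome, lay between 1144 and 1607 normalised counts in CD offspring and between 308 and 543 in WD offspring. The first principal component held 42.5% of the variance and separated the offspring diets, from -116.4 to -49.83 in CD and from 38.08 to 120.7 in WD offspring. Since the labels name no batch, a difference in preparation or batch between the offspring diets cannot be told apart from the diet.

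Cell type markers differed between the libraries. The mean log2 level of the 27 pan-endothelial genes was 11.42 ± 0.03 (SD, n = 3) in CD_CD, 11.1 ± 0.25 in WD_CD, 8.86 ± 2.02 in CD_WD and 8.79 ± 0.64 in WD_WD. Macrophage and monocyte genes averaged 8.93 ± 0.52, 9.45 ± 1.77, 11.54 ± 1.57 and 12.93 ± 0.16 in the same order. The MHC class II presentation genes averaged 8.95 ± 0.74, 9.39 ± 1.34, 14.07 ± 1.71 and 13.28 ± 0.46. For vascular smooth muscle genes the means were 10.11 ± 0.41, 9.09 ± 0.99, 6.38 ± 1.55 and 7.41 ± 0.49. CD_WD replicate 1 stood apart from its group, with list means of 6.55 for endothelial, 4.59 for smooth muscle, 7.58 for fibroblast and 16.02 for MHC class II genes. Its lymphocyte mean, 12.49, was the highest of the 12 libraries, and its macrophage mean, 9.74, the lowest in WD offspring. WD_CD replicate 3 stood apart on the second principal component (11.5% of the variance), at -131.1.

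**Figure D1:**
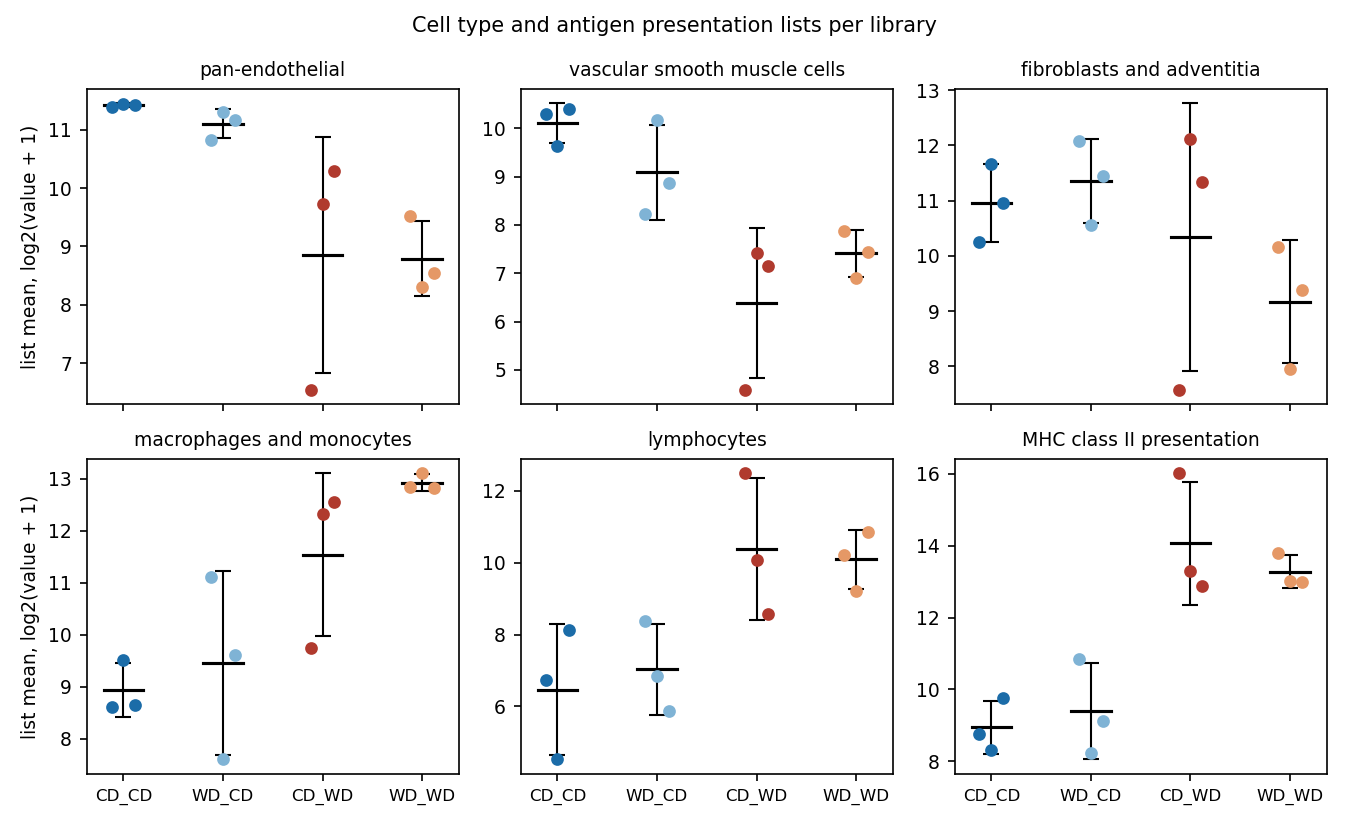
Mean log2 normalised read count of each marker list (vertical axis) in each of the 12 libraries, by group; points are libraries and bars are group means with their SD. Pan-endothelial means were 11.42 in CD_CD and 8.79 in WD_WD, and MHC class II means 8.95 and 13.28; CD_WD replicate 1 lay lowest of all libraries for endothelial genes, at 6.55.

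The first comparison asked how the mother's diet was reflected in aortic endothelial cells of offspring kept on CD. Genes of vascular smooth muscle cells, the contractile cells of the arterial wall, were lower in WD_CD than in CD_CD: 0 of 19 measured members were higher, and the median log2 fold change was -0.99. Myh11, the smooth muscle myosin heavy chain, averaged 3070 ± 910 normalised counts (SD, n = 3) in CD_CD and 1310 ± 943 in WD_CD, Tpm2 (a tropomyosin) 4230 ± 2180 and 1435 ± 1100, and Myl9 (a myosin light chain) 14570 ± 6200 and 6062 ± 5420. None of the 19 passed the test, over all genes or adjusted over the list alone. As a set the list passed limma's camera test (adjusted p = 0.000265). It had adjusted p = 0.982 with an estimated correlation, and adjusted p = 0.503 (median -0.594) without WD_CD replicate 1. Without WD_CD replicate 2 the median was -1.646. Macrophage and monocyte genes were higher for 22 of 25 members (median log2 0.57) but did not pass (camera adjusted p = 0.0639). The other 37 lists did not pass either, with camera adjusted p-values up to 0.978. In the striated muscle list 1 member passed, downward, adjusted over the list alone: Myh1, a skeletal myosin heavy chain, at a log2 fold change of -3.94 ± 1.08 (SE).

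No single gene passed in this comparison: limma called 0 genes (276 at an unadjusted p under 0.05), edgeR 0 (182) and DESeq2 9 (318). Lowest p-values downward belonged to genes nearly absent from WD_CD. In CD_CD replicate 3, 0 of the deposited genes lacked reads, against 168, 164 and 463 in the WD_CD libraries. No deposited gene could thus be absent from all of CD_CD, so near-absence could show only as a fall. Car2, a carbonic anhydrase, averaged 32.2 ± 19.4 in CD_CD and had 1 read in all of WD_CD, a ratio of 228 with a counting interval of 40.9 to 9000 (limma adjusted p = 0.665). Ung, a uracil-DNA glycosylase, had 1 read there (ratio 450, interval 80.7 to 17800, limma adjusted p = 0.775). Hinfp, a regulator of histone genes, had 2 (ratio 229, interval 63.5 to 1890, limma adjusted p = 0.775). Dusp14, a dual-specificity phosphatase, had 0, which makes it at least 22.1-fold lower. Mrs2, a mitochondrial magnesium channel, averaged 88.5 ± 28.2 and 7.04 ± 11.9. Lowest p-values upward were those of Ythdf3, a reader of methylated RNA (184.5 ± 12.4 and 549.8 ± 67.4, log2 1.56 ± 0.37 SE, limma adjusted p = 1), and Srfbp1 (31.5 ± 11.1 and 164.2 ± 56.5, limma adjusted p = 1). Next were Dapp1 (65.4 ± 39.2 and 247.2 ± 130), Pip4k2a (175.2 ± 58.2 and 470.5 ± 104) and Pno1 (76.1 ± 33.2 and 287.7 ± 167), each with limma adjusted p = 1. In the authors' deposited table, 13 genes had an adjusted p under 0.05 (2 higher, 11 lower). Among them were Dusp14 (log2 -8.53, adjusted p = 2.62e-05), Car2 (-7.54, 5.15e-05), Srfbp1 (2.38, 0.000692) and Ythdf3 (1.58, 0.0011). Of those 13, 10 had a library with at most 3 reads (76.9%, against 10.8% of all genes), and limma gave each of the 13 an unadjusted p under 0.05.

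The 17 panel genes described for adhesion, flow response, AP-1 and lipid handling did not pass in CD offspring, each with limma adjusted p = 1. Log2 fold changes for the adhesion molecules and the monocyte chemokine were 0.31 for Vcam1, 0.23 for Icam1, 0.73 for Sele, 0.18 for Selp and -0.11 for Ccl2. Flow-responsive genes had -0.63 (Nos3, endothelial nitric oxide synthase), -0.05 (Klf2) and -0.08 (Klf4). AP-1 genes had 0.12 (Jun), 0.03 (Junb), 0.09 (Fos), 0.11 (Fosl2) and 0.20 (Atf3). Lipid genes had -0.71 (Cyp27a1), 0.37 (Abca1), -0.08 (Abcg1) and -0.58 (Cd36). The sign of 13 of the 17 turned under another setting or without 1 library, so no direction is read from them. Without WD_CD replicate 2 the count of called genes was 3 in place of 0: Rangrf, Tcf19 and Rbpms2, each lower in WD_CD with limma adjusted p = 0.00889 and named after their values were seen. Of the 39 lists, 7 passed camera without CD_CD replicate 2, 3 without WD_CD replicate 2, 2 without CD_CD replicate 3 or WD_CD replicate 3, and 0 without WD_CD replicate 1. Macrophage genes passed without CD_CD replicate 2 (median log2 0.511, camera adjusted p = 0.00503) and without WD_CD replicate 2 (1.221, 1.61e-09), and lymphocyte genes without CD_CD replicate 3 (1.417, 0.000108) and without WD_CD replicate 3 (1.22, 0.00203). MHC class II genes passed without WD_CD replicate 2 (1.299, 0.00444). NF-kB targets (0.39), heat shock (0.196) and fibroblast genes (0.681) upward, and venous (-0.626) and adipocyte genes (-0.463) downward, did so without CD_CD replicate 2.

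The second comparison asked the same of offspring given WD. Muscle and macrophage genes were higher, and fibroblast and MHC class I genes lower, in WD_WD than in CD_WD, by list and not by any single gene. None of these lists passed camera with an estimated correlation (adjusted p = 0.275 for striated muscle and 0.827 for the others). For most of them the size of the difference depended on CD_WD replicate 1. That library had the highest lymphocyte and the lowest macrophage list mean in WD offspring, so these differences partly compare unlike cell mixtures. All 12 striated muscle genes were higher (median log2 1.81). Mb, myoglobin, averaged 39 ± 30.6 (SD, n = 3) in CD_WD and 263.5 ± 101 in WD_WD, and Myl3, a myosin light chain, 14.5 ± 14.7 and 316.5 ± 346. Of 25 macrophage and monocyte genes 24 were higher (median 1.32), such as Cd68, a lysosomal protein of macrophages (12800 ± 11000 and 36670 ± 9850), and Gpnmb, a glycoprotein of lipid-laden macrophages (18550 ± 21300 and 75320 ± 22800). Smooth muscle genes were higher for 17 of 19 (median 0.94), for example Pln, phospholamban (9.25 ± 10.1 and 67.4 ± 34.4). Fibroblast and adventitia genes were higher for only 2 of 18 (median -1.17), with Clec3b at 762.2 ± 692 and 42.6 ± 35.8. MHC class I presentation genes were higher for 0 of 12 (median -0.62), with H2-K1 at 113800 ± 99900 and 35750 ± 17100. The other 32 lists did not pass, with camera adjusted p-values from 0.0943 to 0.923.

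LXR targets and cholesterol efflux genes were higher for 13 of 15 (median log2 0.93), with Npc2, a lysosomal cholesterol carrier, at 5089 ± 1540 in CD_WD and 10400 ± 1470 in WD_WD (SD, n = 3). Fatty acid uptake and PPAR targets were higher for 18 of 26 (median 0.47), with Fabp5, a fatty acid binding protein, at 23840 ± 21500 and 103500 ± 16500. Members that passed adjusted over the list alone were Mb and Myl3 of the striated muscle and Pln of the smooth muscle list. Members of the other lists did not. Camera adjusted p-values were 2.13e-07 for striated muscle, 3.87e-06 for macrophages, 0.000111 for smooth muscle, 0.000111 for MHC class I, 0.000837 for LXR targets, 0.00128 for fibroblasts and 0.0302 for fatty acid uptake. Striated muscle had adjusted p = 0.275 with an estimated correlation, and the other lists had adjusted p = 0.827 with an estimated correlation. Leaving out CD_WD replicate 1, the library with few endothelial reads, gave medians of 0.504 for macrophages (camera adjusted p = 0.0818), 0.07 for smooth muscle (0.466), -0.335 for MHC class I (0.0996), 0.406 for LXR targets (0.0792), 0.027 for fatty acid uptake (0.997) and -2.448 for fibroblasts (4.36e-20). Fibroblasts had a median of -0.311 (adjusted p = 0.579) without CD_WD replicate 2, -0.775 (0.132) without CD_WD replicate 3 and -0.6 (0.243) without WD_WD replicate 2. The smooth muscle median was 1.567, 1.5 and 1.467 without the same 3 libraries. The MHC class I median was -0.926 without CD_WD replicate 3, and that of LXR targets 0.546 without WD_WD replicate 1. Fatty acid uptake had adjusted p = 0.0609, 0.0537 and 0.129 without WD_WD replicates 1, 2 and 3, with a median of 0.258 without the last and 0.903 without CD_WD replicate 2. Striated muscle passed with any of the 6 libraries left out (highest adjusted p = 0.000347). The number of lists that passed was 13, 14 and 15 without CD_WD replicates 1, 2 and 3, against 7. Pan-endothelial genes, with a median of -0.08 (camera adjusted p = 0.825), were among those gained: the median was -1.206 (3.62e-17) without CD_WD replicate 1 and 0.792 (0.00552) without CD_WD replicate 3. Matrix genes (0.17) had -1.432 (6.73e-10), 0.724 (0.0146) and 0.925 (0.00969) without CD_WD replicates 1, 2 and 3, and ribosomal protein genes (-0.17) 0.647 (2.59e-17), -0.532 (9.63e-05) and -0.647 (9.53e-06). With libraries left out singly, laminar-flow and arterial genes passed only without CD_WD replicate 1, at -0.859 (1.44e-07) and -1.073 (1.39e-06). Leukocyte adhesion genes (0.37) had -0.706 (0.000625) and 0.931 (0.00504), and lymphocyte genes (-0.285) 0.699 (0.0357) and -1.252 (0.021), without CD_WD replicates 1 and 3. The direction of the pan-endothelial, matrix, ribosomal, adhesion and lymphocyte lists thus turned with the library left out, and no direction is read from them. MHC class II genes (-0.81) passed without CD_WD replicates 2 and 3, at -1.231 (0.0108) and -1.27 (0.00552).

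Single genes did not pass in WD offspring: limma called 0 (628 at an unadjusted p under 0.05), edgeR 0 (543) and DESeq2 14 (775). Abi3bp, an extracellular matrix protein, came closest, with 585 ± 487 (SD, n = 3) in CD_WD and 4.97 ± 6.17 in WD_WD (log2 -6.78 ± 0.94 SE, limma adjusted p = 0.0836). Next were Zbtb8a and Figf (a vascular endothelial growth factor), which had 3 reads each in WD_WD (ratios 37.9, interval 13 to 184, and 58.6, interval 20.1 to 284; limma adjusted p = 0.506). Atp2a3, a calcium pump (1090 ± 377 and 320.4 ± 27.7), and Spats2l (120.3 ± 73.9 and 6.37 ± 1.42) also had limma adjusted p = 0.506. Upward the lowest p-values were those of Mamdc2 (9 ± 11.6 and 132.8 ± 59.1) and Rmnd5a (94.1 ± 18.3 and 462.8 ± 354), both with limma adjusted p = 0.836. Aprt, adenine phosphoribosyltransferase (1375 ± 192 and 3799 ± 650), Mb and Fbxo32, a muscle ubiquitin ligase (295.5 ± 115 and 1126 ± 253) had the same adjusted p. In the authors' deposited table, 36 genes had an adjusted p under 0.05 (12 higher, 24 lower), led by Abi3bp (log2 -7.14, adjusted p = 4.75e-11). Of the 36, 18 had a library with at most 3 reads (50%, against 14.1% of all genes). In CD_WD replicate 3 only 1 deposited gene lacked reads, against 46, 178 and 202 in the WD_WD libraries. Complete absence from a group could thus hardly show as a rise, while very low levels could. Without WD_WD replicate 1 the limma count was 10, and without CD_WD replicate 1 or WD_WD replicate 3 it was 1, Abi3bp (limma adjusted p = 0.0137 and 0.0315).

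These panel genes did not pass in WD offspring either (limma adjusted p between 0.836 and 0.995). Their log2 fold changes were 0.40 for Vcam1, 0.09 for Icam1, 0.37 for Sele, 0.64 for Selp and 1.42 for Ccl2. Nos3 had -0.19, Klf2 -0.66 and Klf4 -0.13. Jun had -0.49, Junb -1.12, Fos -0.32, Fosl2 0.49 and Atf3 1.29, and Cyp27a1 had 0.03, Abca1 0.94, Abcg1 0.23 and Cd36 0.58. The sign of 10 of the 17 turned under another setting or without 1 library. The effects of the mother's diet in CD and in WD offspring had r = 0.0382 across the 10655 genes (exact permutation p = 0.48, 400 arrangements) and rho = 0.0431 (exact permutation p = 0.5). Of all genes 51.7% had the same sign in both, and no arrangement of the libraries gave an r further from 0 than 0.14.

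The third comparison set WD offspring against CD offspring of CD mothers. Leukocyte and antigen presentation genes were higher, and endothelial, smooth muscle and matrix genes lower, in WD offspring. The largest rises among the genes set by the rule were S100a8 (chromosome 3, 90668978 to 90670035), Irg1 and S100a9. S100a8 and S100a9 are calcium-binding proteins of neutrophils and monocytes, and Irg1 is an itaconate-forming enzyme of activated macrophages. S100a8 averaged 29.5 ± 28.1 (SD, n = 3) in CD_CD and 68880 ± 70000 in CD_WD (log2 11.66 ± 1.57 SE, limma adjusted p = 0.00127), Irg1 had 9.53 ± 1.49 (limma adjusted p = 0.00216), and S100a9 averaged 28.1 ± 15.3 and 16800 ± 17000 (8.80 ± 1.38, limma adjusted p = 0.00224). Next were Cd7, a lymphocyte receptor (7.46, 0.012), Il1r2, an interleukin 1 decoy receptor (7.35, 0.0215), and Ccl4, a chemokine (7.30, 0.00241). Cd7 had limma adjusted p = 0.0557 without CD_CD replicate 1 and 0.0541 without CD_CD replicate 2, and Il1r2 had 0.0975 without CD_CD replicate 1 and 0.0637 without CD_WD replicate 2.

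Of the 9 measured MHC class II presentation genes 8 rose with CD mothers (9 adjusted over the list alone). Cd74 (chromosome 18, 60803848 to 60812652) averaged 10170 ± 4070 (SD, n = 3) in CD_CD and 1053000 ± 1060000 in CD_WD (log2 6.29 ± 0.91 SE, limma adjusted p = 0.00155), and H2-Aa 1934 ± 1010 and 161400 ± 174000 (5.95 ± 0.82, limma adjusted p = 0.00129). Of 25 macrophage and monocyte genes 8 rose (11 adjusted over the list alone), with Fcer1g, an Fc receptor chain, at 847.4 ± 120 and 35970 ± 18800, and Ly6c2, a marker of inflammatory monocytes, at 53.3 ± 29 and 5054 ± 2080. Of 17 lymphocyte genes 8 rose (14), with Nkg7, a protein of cytotoxic cells, at a log2 of 5.87. Of 10 granulocyte and mast cell genes 4 rose (5), with Retnlg, of neutrophils, at 5.33. No member of these 4 lists fell. As sets they were higher, with medians of log2 5.40 for MHC class II (camera adjusted p = 1.7e-08), 2.10 for macrophages (3.82e-06), 3.94 for lymphocytes (1.09e-06) and 2.79 for granulocytes (0.00289), under each scaling tried. They had adjusted p = 0.319 with an estimated correlation, except macrophages with adjusted p = 0.377 with an estimated correlation. The macrophage median was 3.303 without CD_WD replicate 1, and without CD_CD replicate 2 that of granulocytes was 1.64.

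Inflammatory lists were also higher with CD mothers at the deposited scaling. NF-kB feedback targets (8 of 18 rose, 11 adjusted over the list alone, median log2 1.42, camera adjusted p = 2.01e-05), leukocyte adhesion and chemokine genes (7 of 22, 7, 0.74, 0.0248) and interferon response genes (8 of 36, 11, 0.63, 0.00245) were among them. These lists had adjusted p = 0.319, 0.565 and 0.377 with an estimated correlation. With scaling by library totals their medians were -0.02, -0.68 and -0.81. MHC class I presentation genes (8 of 12 rose, 8 adjusted over the list alone, median 1.91, camera adjusted p = 4.94e-06) stayed higher with library totals, at 0.47, and had adjusted p = 0.319 with an estimated correlation. Members that rose included Ccl5, a T cell chemokine (log2 6.83 ± 0.51 SE, limma adjusted p = 7e-05), Il1b, interleukin 1 beta (5.94 ± 1.15, limma adjusted p = 0.00539), Tnfaip2 (3.81), Birc3, an inhibitor of apoptosis (2.63), Zbp1, a sensor of nucleic acids (3.06), and Psmb8, a subunit of the immunoproteasome (2.69). Without CD_CD replicate 3 the adhesion list had camera adjusted p = 0.096 (median 0.422), without CD_WD replicate 2 it had 0.0998, and without CD_WD replicate 3 it had 0.386 (median 0.105). Its median was 1.213 without CD_CD replicate 2 and 2.054 without CD_WD replicate 1, where that of the interferon response was 1.039.

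Genes that mark endothelial cells were lower in WD offspring of CD mothers. These libraries held RNA of several cell types, so a change within endothelial cells was not told apart from the cell mixture. Of 27 pan-endothelial genes 10 fell and 0 rose (19 fell adjusted over the list alone). Ptprb, the vascular endothelial protein tyrosine phosphatase (chromosome 10, 116275523 to 116389535), averaged 11240 ± 784 (SD, n = 3) in CD_CD and 748.9 ± 618 in CD_WD (log2 -4.60 ± 0.75 SE, limma adjusted p = 0.00241). Of 15 genes in the laminar-flow list, named after the flow-induced factors KLF2 and KLF4, 8 fell and 1 rose (12 and 2 adjusted over the list alone). Heg1, a junction protein, was at -3.05 ± 0.34 (limma adjusted p = 0.000541) and Aqp1, a water channel, at -3.48. Of 17 arterial and Notch genes 7 fell (11), with Efnb2, the arterial ephrin, at -3.95, Notch4 at -3.00 and Jag1 at -2.86. Of 13 venous, capillary and lymphatic genes 4 fell (4), with Ephb4 at -3.58 and Flt4 at -4.53. Of 18 angiogenesis genes 7 fell (12) and 1 rose, with the co-receptor Nrp1 at -2.50 and the chemokine receptor Cxcr4 at 4.86. Medians of these lists were -2.70 for pan-endothelial (camera adjusted p = 7.68e-10), -2.29 for laminar flow (1.93e-05), -2.80 for arterial (9.07e-07), -1.81 for venous (0.00461) and -2.49 for angiogenesis (9.38e-05), negative under each scaling tried. They had adjusted p = 0.319 with an estimated correlation, except the venous list with adjusted p = 0.36 with an estimated correlation. Without CD_WD replicate 1 the medians were -1.255, -1.503, -1.551, -0.617 and -1.644 in the same order.

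Smooth muscle genes had the lowest median of the 39 lists with CD mothers, and the matrix list was lower too. Of 19 smooth muscle genes 15 fell (18 adjusted over the list alone). Myh11 (chromosome 16, 14194535 to 14291372) averaged 3070 ± 910 (SD, n = 3) in CD_CD and 53.4 ± 49.1 in CD_WD (log2 -6.20 ± 0.78 SE, limma adjusted p = 0.000999), and Pln had -5.66 and Tagln, transgelin, -4.26. Of 31 extracellular matrix genes 10 fell (12). Eln, elastin (chromosome 5, 134702593 to 134747323), averaged 20320 ± 5300 and 812.4 ± 755 (-5.29 ± 0.82, limma adjusted p = 0.00209), and Fn1, fibronectin, and Col5a2, a collagen chain, had -3.17 and -3.63. Hspb7, a small heat shock protein of muscle (-5.90, limma adjusted p = 0.0124, and 0.0501 without CD_CD replicate 2), Rasl12 (-5.51, 0.0179, and 0.0793 and 0.069 without CD_CD replicates 1 and 2) and Pcdh7, a protocadherin (-5.30, 0.0477), were also among the largest falls. Pcdh7 did not pass without any 1 of CD_CD replicates 1, 2 and 3 (limma adjusted p = 0.133, 0.13 and 0.0938) or CD_WD replicates 1 and 2 (0.145 and 0.0677). Medians were -3.69 for smooth muscle (camera adjusted p = 5.35e-12; adjusted p = 0.319 with an estimated correlation) and -2.32 for matrix (camera adjusted p = 3.26e-07; adjusted p = 0.377 with an estimated correlation), negative under each scaling tried. Both medians were smaller without CD_WD replicate 1, at -2.633 and -1.051 (camera adjusted p = 2.46e-11 and 0.00019). Fibroblast genes did not pass as a list (1 of 18 fell, median -0.57, camera adjusted p = 0.205), nor did striated muscle (3 of 12 fell, 6 adjusted over the list alone, median -2.29, 0.0661). Fibroblast genes passed without CD_WD replicate 2 (median -1.46, camera adjusted p = 0.00614), and striated muscle without CD_CD replicate 1 (0.047), CD_WD replicate 1 (0.0488) or CD_WD replicate 2 (0.0205).

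Genes of mitochondrial respiration and of the ribosome, nearly all of them short, were higher with CD mothers. Of 35 nuclear-encoded oxidative phosphorylation genes 21 rose (25 adjusted over the list alone), with Cycs, cytochrome c, at 692.1 ± 166 (SD, n = 3) in CD_CD and 5806 ± 2240 in CD_WD (log2 3.03 ± 0.34 SE, limma adjusted p = 0.000541) and Ndufa2, of complex I, at 3.32. Of 40 ribosomal protein genes 30 rose (38), with Rpl38 at 3.38 and Rpl41 at 3.28. Medians were 1.55 (camera adjusted p = 1.62e-13) and 2.25 (1.36e-17), positive under each scaling tried, and both lists had adjusted p = 0.319 with an estimated correlation. The ribosomal median was 1.446 without CD_WD replicate 1. Gene length moved with the offspring diet: the median log2 fold change was 1.27 in the decile of shortest genes (median 1021 bp) and -0.84 in that of the longest (8690 bp). With the length trend removed, the medians of both lists were 0.288 and 0.955, and both still passed (camera adjusted p = 0.0168 and 1.05e-07), but only 7 members of each rose, and 1 of oxidative phosphorylation fell.

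**Figure D2:**
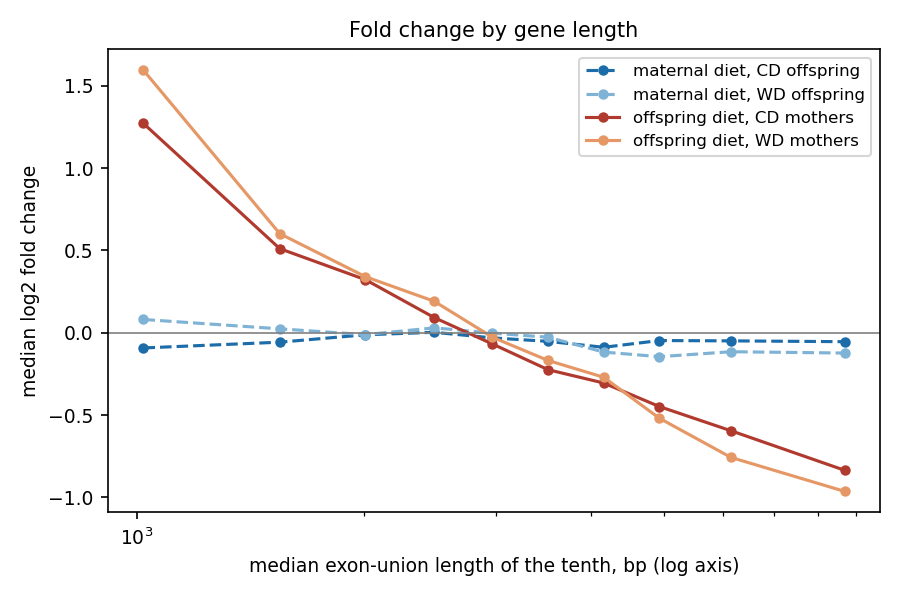
Median log2 fold change (vertical axis) of the genes in each decile of gene length against the median exon-union length of the decile in bp (horizontal axis, log scale); each line is 1 comparison. With CD mothers the offspring diet comparison ran from 1.27 for the shortest to -0.84 for the longest genes, with WD mothers from 1.59 to -0.96, and the maternal diet comparisons lay between -0.15 and 0.08.

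Stress and metabolic lists with CD mothers were higher at the deposited scaling, and each turned negative with library totals: heat shock (5 of 16 rose, 7 adjusted over the list alone, median log2 0.93, camera adjusted p = 0.00088), immediate-early and dissociation response (8 of 26 rose and 1 fell, 12 and 2, 1.07, 0.00479), glycolysis (5 of 16 rose, 6, 0.47, 0.0184), NRF2 antioxidant targets (5 of 19 rose, 6, 0.74, 0.0231) and cell cycle (2 of 30 rose, 0, 1.06, 0.00518). They had adjusted p = 0.319 (heat shock), 0.377 (immediate-early, glycolysis and cell cycle) and 0.412 (NRF2) with an estimated correlation. With library totals their medians were -0.51, -0.38, -0.97, -0.70 and -0.36, and the immediate-early and glycolysis lists also turned with quantile normalisation, to -0.07 and -0.05. Dnajb1, a heat shock co-chaperone, rose by log2 2.39 ± 0.33 (SE, limma adjusted p = 0.00129), Hspe1, a mitochondrial chaperonin, by 3.88 ± 0.62 (0.00226) and Hk2, hexokinase 2, by 3.04 ± 0.44 (0.00154). Chromatin modifiers were lower (3 of 46 fell, 0 adjusted over the list alone, median -0.75, camera adjusted p = 0.00393; adjusted p = 0.319 with an estimated correlation). With the length trend removed they had a median of -0.285 (camera adjusted p = 0.356). Without CD_WD replicate 2, glycolysis had camera adjusted p = 0.0585 (median 0.259) and NRF2 targets 0.0998 (0.463), and without CD_WD replicate 3 the latter had 0.111. Without CD_WD replicate 1 their medians were 0.747 and 1.389, and without CD_CD replicate 2 that of NRF2 targets was 1.122.

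Lists that did not pass with CD mothers held some members that did. Hypoxia targets (3 rose, 1 fell, camera adjusted p = 0.816, median -0.18 but mean 0.18) included Hilpda, a lipid droplet protein (log2 3.65 ± 0.41 SE, limma adjusted p = 0.000541), and Higd1a (2.82 ± 0.41, 0.00157). The mesothelium and epithelium list (2 of 4 rose, 2 adjusted over the list alone, camera adjusted p = 0.0515) rested on Alb, the albumin of liver and plasma (15 ± 10 and 1293 ± 558, SD, n = 3), and Sftpc, a surfactant protein of lung (25 ± 4.86 and 315.2 ± 165). Camera adjusted p-values were 0.0657 for AP-1 subunits, 0.0657 for endothelial-to-mesenchymal transition, 0.0908 for circadian clock, 0.0926 for fatty acid uptake, and 0.0969 for the unfolded protein response. They were 0.144 for erythrocytes and platelets, 0.296 for neurons, 0.639 for senescence, 0.749 for LXR targets, 0.887 for cholesterol synthesis, 0.887 for adipocytes (median -0.03 but mean 0.41) and 0.948 for glucocorticoid targets. Some of these passed without 1 library: AP-1 subunits without CD_CD replicate 1 (0.0289), CD_CD replicate 2 (0.0362) or CD_WD replicate 1 (0.00555), and endothelial-to-mesenchymal transition without CD_WD replicate 2 (0.0221) or 3 (0.0366). Fatty acid uptake (median -0.50) did so without CD_CD replicate 2 (-0.74, 0.0398) or CD_WD replicate 2 (-0.884, 0.0106), and with the length trend removed (-0.77, 0.045). The mesothelium and epithelium list passed without CD_CD replicate 1 (0.04), CD_CD replicate 3 (0.0418) or CD_WD replicate 1 (0.0325). Without the last, the unfolded protein response (0.764, 0.0224) and erythrocyte and platelet genes (2.657, 0.0114) passed too.

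With CD mothers limma called 1599 genes, 1008 higher and 591 lower (63% higher). The median of all genes was -1.45 under scaling by library totals, where 291 genes were higher and 4076 lower (6.66% higher), while quantile normalisation called 1962, with 51% higher. Without CD_CD replicate 1 the count was 698 and without CD_CD replicate 2 it was 705.

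The fourth comparison set WD offspring against CD offspring of WD mothers. Chil3, a chitinase-like protein of macrophages, averaged 10.2 ± 17.6 (SD, n = 3) in WD_CD and 4256 ± 3060 in WD_WD (log2 10.09 ± 1.96 SE, limma adjusted p = 0.00381), and S100a8 (9.59, 0.00165), S100a9 (9.40, 0.00095) and Il1a, interleukin 1 alpha (8.99, 0.00508), were also among the largest rises. Trem1, an activating receptor of myeloid cells (chromosome 17, 48232768 to 48246924), had 0 reads in WD_CD and 1268 ± 1340 in WD_WD, at least 850-fold higher (limma adjusted p = 0.000257). Car2 had 1 read in WD_CD and 1205 ± 919 in WD_WD, a ratio of 8520 with a counting interval of 1530 to 337000 (limma adjusted p = 8.63e-05). Macrophage and monocyte genes rose for 16 of 25 (19 adjusted over the list alone), with Tyrobp, an adaptor of myeloid receptors, at 1908 ± 1660 and 75530 ± 18500. MHC class II genes rose for 8 of 9 (8), with Cd74 at 21110 ± 20000 and 359100 ± 175000 and H2-Aa at a log2 of 4.34. Lymphocyte genes rose for 3 of 17 (3), with Nkg7 at 6.80 and Gzma, granzyme A, at 6.07. Medians were 3.56 for macrophages (camera adjusted p = 5.77e-07), 4.19 for MHC class II (4.55e-05) and 2.68 for lymphocytes (0.00137), positive under each scaling tried, and the 3 lists had adjusted p = 0.482 with an estimated correlation. Granulocyte genes rose for 5 of 10 (5) but did not pass as a list (median 3.26, camera adjusted p = 0.0673), except without WD_CD replicate 1 (0.0212) or WD_WD replicate 2 (0.0442).

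Vessel wall genes were lower with WD mothers too, again without being told apart from the cell mixture. Abi3bp (chromosome 16, 56477878 to 56690135) fell from 473.4 ± 97.1 (SD, n = 3) in WD_CD to 4.97 ± 6.17 in WD_WD (log2 -6.97 ± 0.94 SE, limma adjusted p = 0.000641), and Mmrn1, a multimerin of endothelial cells, from 1490 ± 722 to 38 ± 59.7 (-6.71 ± 1.16, limma adjusted p = 0.00199). Klk10, a kallikrein-related peptidase, fell from 4443 ± 1290 to 187.6 ± 212 (-6.34 ± 1.57, limma adjusted p = 0.0131). Hoxb2 (-6.84, 0.0158), Epdr1 (-6.25, 0.00994) and Zfp423 (-6.06, 0.0276) were the other largest falls. Hoxb2 did not pass without WD_CD replicates 2 or 3 or WD_WD replicates 2 or 3 (limma adjusted p = 0.0519, 0.0503, 0.0561 and 0.0539), and neither did Zfp423 (0.0791, 0.0709, 0.0977 and 0.0943). Pan-endothelial genes fell for 13 of 27 (17 adjusted over the list alone), with Pecam1, an endothelial junction protein, at 23040 ± 4310 and 3328 ± 880 and Cdh5, VE-cadherin, at 2218 ± 887 and 155.7 ± 131. Laminar-flow genes fell for 8 of 15 and rose for 1 (11 and 2), and arterial and Notch genes fell for 7 of 17 (12). Venous genes fell for 4 of 13 with 1 that rose (5 and 1), and angiogenesis genes for 5 of 18 with 1 that rose (6 and 1). Matrix genes fell for 14 of 31 and rose for 1 (18 and 1), with Timp3, a protease inhibitor, at -3.96. Fibroblast genes fell for 5 of 18 (5), with Col1a2, a collagen I chain, at -3.81, and smooth muscle genes for 4 of 19 (6), with Itga8, an integrin, at -4.22.

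Medians of these lists with WD mothers were log2 -2.29 for pan-endothelial (camera adjusted p = 5.77e-07), -2.61 for laminar flow (0.000302), -2.56 for arterial (1.42e-05), -1.68 for venous (0.0346), -1.59 for angiogenesis (0.00534), -2.63 for matrix (1.42e-05), -1.83 for fibroblasts (0.00156) and -1.88 for smooth muscle genes (0.00211), negative under each scaling tried. They had adjusted p = 0.482 with an estimated correlation. The venous list had camera adjusted p = 0.0585 (median -1.114) without WD_WD replicate 2, and the smooth muscle median was -1.178 without WD_CD replicate 2. Circadian clock genes were lower (7 of 16 fell and 1 rose, 8 and 1 adjusted over the list alone, median -1.58, camera adjusted p = 0.0297; adjusted p = 0.482 with an estimated correlation, and camera adjusted p = 0.0506 without WD_CD replicate 2). Tef, a clock output factor, was at -4.29 ± 0.57 (SE, limma adjusted p = 0.000568) and Per3, a period gene, at -4.19 ± 1.10 (0.0165). Chromatin modifiers were lower as well (6 of 46 fell and 1 rose, 5 and 0, median -0.72, camera adjusted p = 0.00455; adjusted p = 0.482 with an estimated correlation), and had a median of -0.341 (camera adjusted p = 0.307) with the length trend removed.

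Oxidative phosphorylation genes rose for 24 of 35 with WD mothers (26 adjusted over the list alone, median log2 1.68, camera adjusted p = 4.56e-13), with Cycs at 657.3 ± 186 (SD, n = 3) in WD_CD and 5433 ± 227 in WD_WD. Ribosomal protein genes rose for 32 of 40 (36, median 2.26, camera adjusted p = 4.56e-13). Both medians were positive under each scaling tried, and both lists had adjusted p = 0.482 with an estimated correlation. With the length trend removed their medians were 0.419 and 0.512, and both still passed (camera adjusted p = 0.0237 and 0.00325), but only 7 and 5 members rose, and 2 of oxidative phosphorylation fell. Higher at the deposited scaling, but negative with library totals, were NF-kB targets (8 of 18 rose, 9 adjusted over the list alone, 1.22, camera adjusted p = 0.00455), interferon response (10 of 36 rose and 1 fell, 11 and 1, 0.82, 0.00534) and glycolysis (8 of 16 rose, 9 and 2 fell adjusted over the list alone, 1.21, 0.00912). So were NRF2 targets (8 of 19 rose and 1 fell, 9 and 1, 1.21, 0.0101), immediate-early genes (7 of 26 rose and 1 fell, 7 and 2, 0.81, 0.0178), cell cycle (5 of 30 rose, 5, 0.92, 0.0364), MHC class I (4 of 12 rose, 5, 0.92, 0.0407) and heat shock (5 of 16 rose, 5, 0.80, 0.0453). These lists had adjusted p = 0.482 with an estimated correlation, and MHC class I had adjusted p = 0.536 with an estimated correlation. With library totals the lowest of these medians was -0.59 (heat shock), and the immediate-early and heat shock lists turned with quantile normalisation too, to -0.34 and -0.06. Members that rose included Il1b (6.80), Zbp1 (4.14), Oasl1, an interferon-induced gene (6.71), Hk2 (3.15), Hist1h1b, a linker histone (7.39), and Tpx2, a spindle protein (5.48). Camera adjusted p-values without 1 library rose above 0.05 for heat shock (0.0704, 0.0853, 0.0722 and 0.0611 without WD_CD replicates 1 and 2 and WD_WD replicates 1 and 2) and MHC class I (0.082, 0.0673 and 0.122 without WD_CD replicates 2 and 3 and WD_WD replicate 1, with a median of 0.562 without the last). They did so too for immediate-early genes (0.072 and 0.0845 without WD_CD replicate 1 and WD_WD replicate 2), cell cycle (0.0947 and 0.156 without WD_CD replicate 3 and WD_WD replicate 3) and interferon response (0.0724 without WD_WD replicate 3).

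The mesothelium and epithelium list passed with WD mothers on Alb (37.3 ± 36.9 and 2425 ± 1340, SD, n = 3) and Sftpc (36.1 ± 12.6 and 670.2 ± 356), neither of them a mesothelial gene (2 of 4 rose, 2 adjusted over the list alone, camera adjusted p = 0.0406; adjusted p = 0.482 with an estimated correlation). It had camera adjusted p = 0.0767, 0.0595 and 0.0514 without WD_CD replicate 1, WD_WD replicate 1 and WD_WD replicate 3. LXR targets (4 of 15 rose, 2 fell, camera adjusted p = 0.08), leukocyte adhesion (8 of 22 rose, 1 fell, 0.0537) and fatty acid uptake (3 of 26 rose, 1 fell, 0.93) did not pass, though Fabp5 rose by log2 6.56 ± 0.81 (SE, limma adjusted p = 0.000415) and Cpt1a, which imports fatty acids into mitochondria, fell by 2.30 ± 0.43 (0.00296). Camera adjusted p-values were 0.101 for AP-1 subunits, 0.101 for erythrocytes and platelets, 0.138 for the unfolded protein response, and 0.175 for neurons. They were 0.201 for cholesterol synthesis, 0.279 for adipocytes, 0.323 for endothelial-to-mesenchymal transition, 0.359 for hypoxia targets, 0.41 for glucocorticoid targets (median 0.19, mean -0.64), 0.509 for senescence and 0.735 for striated muscle (median -0.80, mean 0.89). Leukocyte adhesion passed without WD_CD replicate 2 (0.0445), WD_WD replicate 1 (0.0484) or WD_WD replicate 3 (0.0362), AP-1 subunits without WD_WD replicate 3 (0.0376), erythrocyte and platelet genes without WD_WD replicate 2 (0.0339), and LXR targets with the length trend removed (0.026).

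With WD mothers limma called 2604 genes, 1516 higher and 1088 lower (58.2% higher). Under scaling by library totals the median of all genes was -1.36, and 440 genes were higher and 4271 lower (9.34% higher). Without WD_CD replicate 2 the count was 1593 and without WD_CD replicate 3 it was 1723. The offspring diet comparisons share no library. Of their called genes, 825 were higher in both, against 143 expected of independent lists, 411 were lower in both, against 60.3 expected, and 0 were opposite. Across genes, which are not independent replicates, both sets of fold changes had r = 0.763.

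The interaction asked whether the effect of the mother's diet differed between offspring diets. Smooth muscle genes had a positive interaction for 18 of 19 (median log2 2.19). They were lower with WD mothers in CD offspring (median -0.99), and the 0.94 in WD offspring was 0.07 without CD_WD replicate 1. The interaction was 1.197 without that library. Tpm2 had 3.50 ± 1.18 (SE), Myh11 3.20 ± 1.10 and Ppp1r14a, an inhibitor of myosin phosphatase, 2.16 ± 0.67, each with limma adjusted p = 0.997. Striated muscle (median 1.71), LXR target (0.76) and fatty acid uptake genes (0.60) also had positive medians, and MHC class I (-0.74), fibroblast (-1.32) and MHC class II genes (-1.53) negative ones, with 0 members past the threshold over all genes or adjusted over the list alone. Camera adjusted p-values were 2.06e-08 for smooth muscle, 0.000336 for MHC class I, 0.000581 for fibroblasts, 0.000581 for striated muscle and 0.0226 for each of MHC class II, LXR targets and fatty acid uptake. These 7 lists had adjusted p = 0.919 with an estimated correlation. Smooth muscle, striated muscle and MHC class I passed with any 1 of the 12 libraries left out, while fibroblasts did not without CD_WD replicate 2 (adjusted p = 0.124) or WD_WD replicate 2 (0.0795). The fibroblast medians there were -0.412 and -0.751. Without CD_WD replicate 1, MHC class II had a median of -0.611 (adjusted p = 0.673), fatty acid uptake 0.079 (0.764), LXR targets 0.37 (0.269), MHC class I -0.442 (0.0312) and fibroblasts -2.642 (2.94e-19). The pan-endothelial interaction, 0.31 with all libraries (0.707), was -0.791 (1.58e-08) there and 1.077 (0.0014) without CD_WD replicate 3. Macrophage genes (0.74) passed without WD_CD replicate 1 (1.505, 0.000196), CD_WD replicate 2 (1.319, 0.00793) or CD_WD replicate 3 (1.101, 0.00255). MHC class II also missed the threshold without CD_CD replicates 1 and 2 (0.0544 and 0.0863), WD_CD replicate 1 (0.446, median -0.821) and WD_WD replicates 2 and 3 (0.0879 and 0.118). Fatty acid uptake missed it without CD_CD replicate 1 (0.0697), WD_CD replicate 3 (0.0692) and WD_WD replicates 1, 2 and 3 (0.0537, 0.051 and 0.117), with a median of 0.988 without CD_WD replicate 2, and LXR targets without CD_CD replicate 2 (0.0783), WD_CD replicate 2 (0.236) and WD_WD replicates 1 and 2 (0.0887 and 0.0795). The number of lists that passed was 14 without CD_WD replicate 1, 13 without CD_WD replicate 3 and 4 without WD_WD replicate 2. The other 32 lists did not pass, with adjusted p-values from 0.115 to 0.979.

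Single genes did not pass the interaction: limma called 0 (342 at an unadjusted p under 0.05), edgeR 0 (306) and DESeq2 10 (453). The lowest p-values were those of Car2 (log2 5.17 ± 1.14 SE), Ung (6.06 ± 1.47), Hinfp (6.38 ± 1.56), Guca1a (5.43 ± 1.39) and Lrp12 (6.31 ± 1.63) upward, each with limma adjusted p = 0.997. Downward they were those of Abi3bp (-6.65 ± 1.33), Zbtb8a (-6.63 ± 1.45), Figf (-5.92 ± 1.51), Ift80 (-4.61 ± 1.24) and Spats2l (-3.82 ± 1.06), each with limma adjusted p = 0.997. Car2, Ung and Hinfp were nearly absent from WD_CD and present in the other groups, and Abi3bp averaged 534 ± 192, 473.4 ± 97.1 and 585 ± 487 (SD, n = 3) in CD_CD, WD_CD and CD_WD but 4.97 ± 6.17 in WD_WD.

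Apoe, apolipoprotein E, made by macrophages and smooth muscle cells (chromosome 7, 19696109 to 19699188), was chosen after its values were seen, as were the other genes set beside it. Its normalised counts were 22941, 1889 and 37190 in the replicates of CD_CD and 1803, 52603 and 2458 in those of WD_CD. They were 3232, 4848 and 303332 in CD_WD and 803268, 11184 and 133580 in WD_WD. Lyz2, a lysozyme of myeloid cells, had 34320, 288799 and 376491 in CD_WD and 719905, 588993 and 417244 in WD_WD. In CD offspring some genes of lipid-laden macrophages were high where Apoe was low, so that replicate 2 of each group lay nearer to the other group. Spp1, osteopontin, had 852, 17059 and 151 in CD_CD and 19180, 110 and 18403 in WD_CD. Gpnmb had 133, 4931 and 245 in CD_CD and 10745.5, 224 and 4401 in WD_CD, and Trem2, a lipid receptor, 1.73, 294 and 41 in CD_CD and 1410, 2.79 and 349 in WD_CD. Apoc1, another such gene, did not follow, with 21.2, 24.5 and 75.5 in CD_CD and 292, 20.3 and 62.9 in WD_CD.

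**Figure D3:**
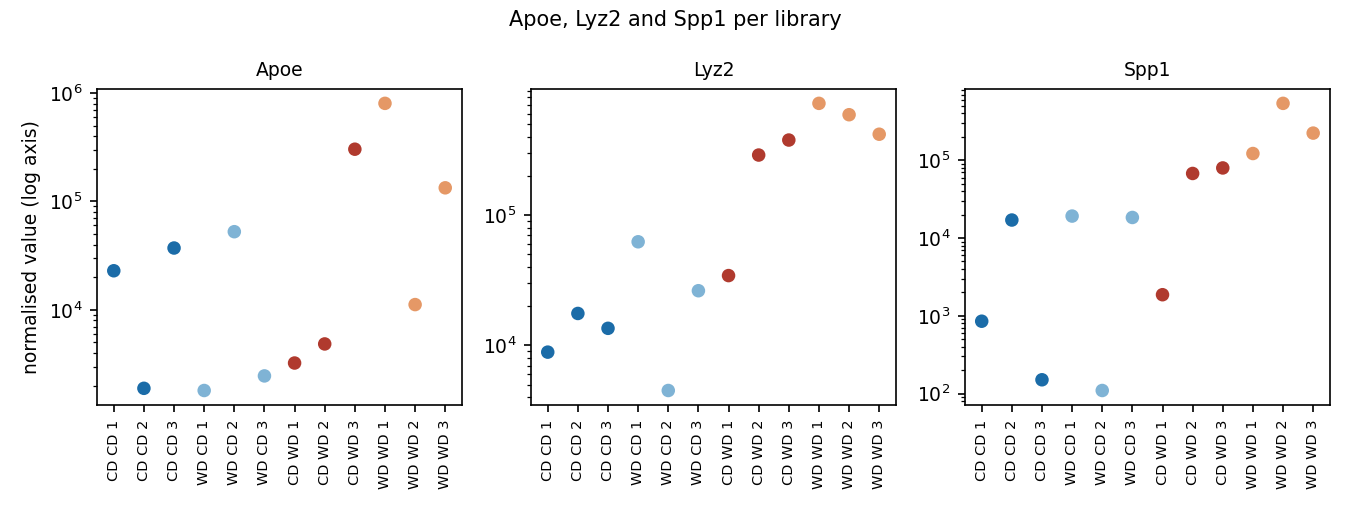
Normalised read counts of Apoe, Lyz2 and Spp1 (vertical axis, log scale) in each of the 12 libraries, by group; points are libraries. Apoe lay at 11184 in WD_WD replicate 2 and at 803268 in WD_WD replicate 1, while Lyz2 lay at 588993 and 719905 in the same libraries.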

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

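Of the tests in this part, those of library scaling, of the length trend on the endothelial and MHC class II lists, of dilution by leukocytes and of other splits of the libraries were chosen only after the result was seen, and so was the endothelial and MHC class II pattern itself.

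By the camera test of the interaction at its preset correlation, 7 gene lists passed, but each had adjusted p = 0.919 with an estimated correlation, and 0 of their members passed. Smooth muscle genes had a median interaction of log2 2.186, striated muscle genes 1.713, LXR target and cholesterol efflux genes 0.76 and fatty acid uptake genes 0.602. MHC class I genes had -0.736, fibroblast genes -1.323 and MHC class II genes -1.534. Without CD_WD replicate 1 and WD_CD replicate 3, camera adjusted p-values were 0.000728 for smooth muscle, 0.034 for MHC class I, 4.07e-16 for fibroblasts and 0.000414 for striated muscle, but 0.594 for MHC class II, 0.262 for LXR targets and 0.833 for fatty acid uptake. Without CD_WD replicate 1 alone the medians were 1.197 for smooth muscle, 1.608 for striated muscle, 0.37 for LXR targets, 0.079 for fatty acid uptake, -0.442 for MHC class I, -2.642 for fibroblasts and -0.611 for MHC class II, so that most of these differences rested in part on that library.

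Endothelial genes were lower and MHC class II genes higher in every library of WD offspring than in any of CD offspring, with smallest gaps of log2 0.529 and 2.04. Macrophage genes did not part the diets in this way: their gap was -1.39, and -2.16 with quantile normalisation and -3.37 with library totals. With library totals or quantile normalisation the smallest gap of the endothelial and MHC class II lists was still at least 0.785. It was 0.372 with the length trend removed. Both values argue against scaling and length as the whole cause. With every library thinned to the depth of the shallowest it was 0.561. Thinning keeps the expected level of each gene, so it speaks only to the number of reads, not to input amount or library complexity. A difference in preparation, RNA quality or batch between the offspring diets would pass all of these checks, and cannot be told apart from the diet. A candidate explanation is a larger share of leukocytes, which would lower endothelial and fibroblast genes alike; the fibroblast minus endothelial mean was -0.0972 ± 0.857 (SD, n = 6) in CD and 0.932 ± 0.881 in WD offspring, and with an exact permutation p = 0.0649 (two-sided) this remained open. Of the measured genes, another list holds 6 of 27 pan-endothelial, 0 of 9 MHC class II and 2 of 25 macrophage genes, each gene had reads in at least 9 of the 12 libraries, and the labels name no sort that would remove leukocytes. A change within the endothelial cells through the offspring diet was not tested apart from the cell mixture.

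Short genes were higher in WD offspring: the shortest minus the longest decile ran from log2 -1.40 to -0.84 in the libraries of CD offspring and from 0.82 to 1.57 in those of WD offspring. After thinning the smallest gap between the diets was 1.65. This speaks only to the number of reads, not to input amount or library complexity. With the length trend removed, the oxidative phosphorylation list had medians of 0.288 with CD mothers and 0.419 with WD mothers, inside the ranges of 10000 random lists of like expression (-0.0638 to 0.928 and -0.0775 to 0.906). Ribosomal protein genes had 0.955 and 0.512, inside 0.299 to 1.2 and 0.157 to 1.14. Both lists still passed camera there, however, with adjusted p = 0.0168 and 0.0237 for oxidative phosphorylation and 1.05e-07 and 0.00325 for ribosomal proteins. The trend with gene length may thus account for much of these rises, but whether for all of them is left open, and its own origin, in RNA quality, library preparation or biology, was not tested.

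Other splits of the same libraries were counted. The 6 libraries of each comparison give 10 splits, too few for a share under 0.05. A real count of 0 is reached by every split, so that the count says nothing about chance for the mother's diet or the interaction. With CD offspring these were 10 of 10 splits, and the highest other gave 2 genes. With WD offspring they were 10 of 10, and the highest other gave 161 genes, for CD_WD replicate 1 with WD_WD replicates 2 and 3 against the rest, which points to a structure of these samples other than the mother's diet. For the offspring diet, 1 of 10 splits gave as many, the real one, with 1599 genes against a highest other of 0 with CD mothers and 2604 against 0 with WD mothers. For the interaction they were 100 of 100 drawn splits, with a highest other of 3. At an unadjusted p under 0.05, where the outcome was not fixed, 8 of 10 splits gave at least the real 276 genes in CD offspring (highest other 428) and 6 of 10 the 628 in WD offspring (1277). For the interaction 69 of 100 gave at least the real 342 (highest other 1013), so that chance is not excluded there.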

How the results depend on the processing

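Library-total scaling, edgeR, removal of the length trend and leaving out both libraries that stood apart (CD_WD replicate 1 and WD_CD replicate 3) were chosen after seeing the data. Where a value below moved, the cause was not tested. The mother's diet gave 0 genes by limma with quantile normalisation, no filter (which removed 0 genes), a pseudocount of 0.1, a fit to the 6 libraries compared, edgeR, library totals and the length trend removed. DESeq2 gave 9 genes in CD offspring, 14 in WD offspring and 10 for the interaction. In WD offspring the count was 1 with the replicate block (Abi3bp, limma adjusted p = 0.0484) and 1 without both libraries that stood apart (Abi3bp, 0.0368). With CD mothers the offspring diet gave 4367 genes with library totals (882 shared with the 1599 in the same direction) and 930 with the length trend removed (781 shared). With WD mothers it gave 4711 (1528 shared with the 2604) and 1661 (1323 shared). Leaving out 1 library, counts ran from 0 to 3 (mother's diet, CD offspring), 0 to 10 (WD offspring), 698 to 1714 (offspring diet, CD mothers), 1593 to 2310 (WD mothers) and 0 to 0 (interaction). Under the other settings the offspring diet counts lay within 1.5 times the values given. The replicate numbers do not pair the libraries: r between libraries of like number ran from -0.232 to 0.074, with 0 of 18 pairs over 0.1. The correlation of both effects of the mother's diet was 0.0382 with the replicate block (exact permutation p = 0.8), 0.0872 for the 5328 genes of higher expression (p = 0.52), 0.041 with the length trend removed (p = 0.44) and 0.00168 to 0.0707 with 1 library left out.

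With an estimated correlation 0 lists passed in CD offspring, 0 in WD offspring, 0 with CD mothers, 0 with WD mothers and 0 for the interaction. With fry 0 passed for the mother's diet in CD offspring, 0 in WD offspring and 0 for the interaction, against 22 and 17 for the offspring diet. Without both libraries that stood apart 4 lists passed in CD offspring, 12 in WD offspring and 14 for the interaction, of which 1, 2 and 4 were among those given. Those gained in CD offspring were pan-endothelial (median log2 -0.282, camera adjusted p = 0.013), macrophages (0.417, 0.0368) and lymphocytes (1.22, 0.000448). In WD offspring they were pan-endothelial (-1.206, 1.19e-15), extracellular matrix (-1.432, 5.65e-09), laminar flow (-0.859, 4.32e-07), arterial (-1.073, 4.02e-06), glucocorticoid targets (-0.749, 0.000289), leukocyte adhesion (-0.706, 0.00107) and neurons (-1.3, 0.00392) downward, and ribosomal proteins (0.647, 1.51e-15), oxidative phosphorylation (0.418, 1.61e-06) and lymphocytes (0.699, 0.036) upward. For the interaction they were the same lists but for lymphocytes, with circadian clock (-1.241, 0.0169), each in the direction given and pan-endothelial at -0.881 (1.63e-06). In WD offspring these rest on CD_WD replicates 2 and 3 alone, and without CD_WD replicate 3 the medians were 0.792 (pan-endothelial, 0.00552), 0.925 (matrix, 0.00969), -0.647 (ribosomal proteins, 9.53e-06), 0.931 (leukocyte adhesion, 0.00504) and -1.252 (lymphocytes, 0.021). In WD offspring striated muscle (camera adjusted p = 3.78e-06) and fibroblasts (4.02e-18) stayed past the threshold there, while macrophages had 0.097, smooth muscle 0.507, MHC class I 0.12, LXR targets 0.097 and fatty acid uptake 0.948. With WD mothers, cell cycle had 0.155 and mesothelium and epithelium 0.0507. Lists that passed with 1 library left out numbered 0 to 7 (CD offspring), 5 to 15 (WD offspring) and 4 to 14 (interaction). With the length trend removed, leukocyte adhesion (camera adjusted p = 0.0595) and NRF2 targets (0.0614) did not pass with CD mothers, though their medians hardly moved (0.757 from 0.74, and 0.738 from 0.742). Nor did MHC class I (0.238, median 0.371 from 0.923), circadian clock (0.0699, -1.168 from -1.584) and mesothelium and epithelium (0.11, 2.267 from 3.37) with WD mothers. Ribosomal proteins passed downward there in WD offspring (-0.331, 0.00179) and for the interaction (-0.307, 0.0155).

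Calls of the genes named for the offspring diet kept their direction under each setting. Those lost were Cd7 (edgeR, adjusted p = 0.0511), Il1r2 (pseudocount of 0.1, 0.0522; edgeR, 0.061), Rasl12 (without both libraries that stood apart, 0.051), Sftpc with CD mothers (length trend removed, 0.0784), Cd74 with WD mothers (quantile normalisation, 0.0854), Epdr1 (edgeR, 0.0646) and Zfp423 (DESeq2, 0.115; edgeR, 0.175; length trend removed, 0.0559). Pcdh7 was lost with a pseudocount of 0.1 (0.115), the replicate block (0.0648), the 6 libraries compared (0.0514), edgeR (0.0533), the length trend removed (0.118) and without both libraries that stood apart (0.163).

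Panel genes reversed for the mother's diet, none past the threshold (limma, edgeR and DESeq2). In CD offspring log2 fold changes with quantile normalisation were -0.028 (Junb) and -0.04 (Fos), and with library totals -0.004 (Junb). With DESeq2 they were 0.385 (Ccl2), -0.011 (Junb), -0.017 (Fos), -0.039 (Fosl2) and 0.129 (Abcg1), and with edgeR 0.396 (Ccl2), -0.003 (Junb), -0.011 (Fos), -0.029 (Fosl2) and 0.139 (Abcg1). Without both libraries that stood apart they were 0.047 (Ccl2) and 0.035 (Klf4). In WD offspring quantile normalisation gave -0.072 (Icam1) and -0.022 (Cyp27a1), and the length trend removed -0.017 (Cyp27a1). DESeq2 gave -0.666 (Vcam1), -0.297 (Icam1), -0.568 (Sele) and -0.355 (Selp), and edgeR -0.72, -0.349, -0.629 and -0.411 for the same genes. Without both libraries that stood apart the values were -1.108 (Vcam1), -0.717 (Icam1), -1.118 (Sele), -0.858 (Selp), -0.216 (Cyp27a1) and -0.146 (Cd36).

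With 1 library left out, values in CD offspring ran from -0.204 to 0.54 (Icam1), -0.008 to 1.463 (Sele), -0.082 to 0.54 (Selp), -0.976 to 0.615 (Ccl2), -0.184 to 0.089 (Klf2), -0.163 to 0.035 (Klf4), -0.166 to 0.284 (Jun), -0.266 to 0.208 (Junb), -0.391 to 0.34 (Fos), -0.18 to 0.587 (Fosl2), -0.355 to 0.604 (Atf3), -1.207 to 0.156 (Cyp27a1) and -0.641 to 0.479 (Abcg1). In WD offspring they ran from -1.108 to 1.48 (Vcam1), -0.717 to 0.888 (Icam1), -1.118 to 1.731 (Sele), -0.858 to 1.69 (Selp), -1.314 to 0.736 (Nos3), -0.918 to 0.374 (Klf4), -0.845 to 0.051 (Fos), -0.216 to 0.474 (Cyp27a1), -0.134 to 0.417 (Abcg1) and -0.146 to 1.11 (Cd36). At a 4-fold change the simulated recovery for the mother's diet was 10% in CD and 1% in WD offspring, so that changes of that size were mostly not detectable with 3 libraries per group.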

Other observations

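The tests of the Apoe pattern in this part were chosen only after the result was seen.

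Glucocorticoid targets held members that fell in WD offspring of WD mothers, although the list did not pass. Klf9, a glucocorticoid-induced transcription factor, averaged 1993 ± 674 normalised counts (SD, n = 3) in WD_CD and 180.8 ± 94.7 in WD_WD (log2 -3.55 ± 0.64 SE, limma adjusted p = 0.00249). Zbtb16, another such factor, averaged 311.2 ± 131 and 23.5 ± 13.1 (-3.76 ± 0.81, limma adjusted p = 0.00682). Of the 15 members measured, 6 fell and 2 rose. Among endothelial genes, Lyve1, a hyaluronan receptor of lymphatic endothelium and some macrophages, averaged 1911 ± 430 and 134.4 ± 109 (-4.68 ± 1.08, limma adjusted p = 0.0092). Ddit3, a transcription factor of the stress response, averaged 252.2 ± 121 and 2659 ± 655 (3.49 ± 0.42, limma adjusted p = 0.000393), while the unfolded protein response list as a whole did not pass.

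Apoe levels differed within groups, from 1889 to 37190 in CD_CD, 1803 to 52603 in WD_CD, 3232 to 303332 in CD_WD and 11184 to 803268 in WD_WD. If the share of macrophages set them, Apoe would follow the mean of the macrophage list within groups, but r was -0.174, and its departure from that mean (root mean square, log2) was 2.77, against at most 1.89 (Spp1) and a median of 0.667 for the 25 members. Apoe was chosen after its values were seen, and other forms of this test were tried before it. A large departure was thus partly built in. The test does not decide on the share, and a difference in macrophage state stays open too. From the smooth muscle list it departed by 1.98, against at most 1.45 (Lmod1) for 19 members. It moved with that list (r = 0.675) but by more, which for the same reason does not decide on the smooth muscle share. In CD offspring, replicate 2 of each group lay nearer to the other group in Apoe and, the other way round, in Spp1, Gpnmb and Trem2, as an exchange of these labels would need. The list means went the same way: macrophages had 8.61, 9.52 and 8.65 in CD_CD and 11.12, 7.6 and 9.62 in WD_CD, and smooth muscle 10.29, 9.64 and 10.4 and 8.23, 10.17 and 8.87, though the 9.64 lay nearer to its own group. Apoc1 did not follow. With the labels exchanged, 428 genes had an unadjusted p under 0.05 by limma, the highest of the 10 splits, against 276 as given and at most 384 among the rest (SD 54.5 over these 9). A lead within that SD leaves it open, and exchanged labels cannot be told apart from a difference in cells between these libraries. The exchange would leave the ranges in CD_WD and WD_WD as they are. The labels give no genotype, and no biological explanation was tested.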
